A study of Oryza sativa with 6 samples.

How the data were processed

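The samples were 6 two-colour arrays of rice (cultivar Koshihikari). Per the labels, plants were kept at 26 °C by day and 20 °C by night from the booting stage, aleurone cells and central starchy endosperm were collected at 7 days after flowering by laser microdissection, and 2.5 ng of total RNA per sample was amplified from an oligo-dT primer and labelled with Cy3 or Cy5. The array design carries 45151 spots, with 41908 gene probes for 29690 loci, 510 probes for microRNAs, 59 design control probes and 60 manufacturer's control probes, of which 10 are spike-in probes.

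Per the file headers, the deposited scanner files hold median spot and local background intensity values for each dye, made with Agilent Feature Extraction 9.1.3.1 for replicates 1 and 2 and 9.5.3.1 for replicate 3, without further normalization of those columns. The same files hold the software's LogRatio, which per the file headers is the log10 ratio of Cy5 over Cy3 after the software's background detrending and dye normalization. The deposited series table holds log10 ratios too. On 3 arrays they equalled the LogRatio (r = 1) and on the dye-swapped 3 its negative (r = -1, largest difference 5e-06), so that every column is central starchy endosperm over aleurone. Each of its column medians was 0. The median rather than the mean foreground was used on all arrays because 3 files lack the mean, as fixed beforehand. The number of arrays, not a count of molecules, limits the precision, and the share of probes above background is the measure of signal per sample.

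The 2 arrays of a replicate were taken as a technical dye swap, following the series design and the replicate numbers in the sample titles. The numbers were also checked in the values. After subtracting the mean of the 3 arrays of the same dye orientation, the arrays of the same number correlated with r of 0.711, 0.449 and 0.405, all above the threshold of 0.1 set for pairing. Replicate 2 with aleurone in Cy3 also passed it with replicate 3 with aleurone in Cy5 (r = 0.362), and the other unlike pairs were negative. Without the subtraction, the Cy3-aleurone arrays of replicates 1 and 2 correlated slightly better with another replicate's swap (0.913 and 0.907) than with their own (0.859 and 0.904). That of replicate 3 correlated best with its own (0.960). The values alone therefore do not settle the pairing. The 3 replicates, each the mean of its 2 arrays, correlated with r of 0.925, 0.912 and 0.957 across probes. Replicates 1 and 2 were on one slide and replicate 3 on the other, as the scanner files show.

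Intensities were background-corrected with the normexp method (offset 50) and normalised within arrays by loess (span 0.3, weight 0 for control spots) in limma 3.58.1 with statmod 1.5.0 under R 4.3.3. Spots marked as outliers by the scanner software were left out, spots of the same probe were averaged, and ratios were turned to aleurone over central starchy endosperm. The offset draws the ratios of dim probes toward 0. A probe was tested when well above background in the same region on both arrays of at least 2 of the 3 replicates. This left 18914 probes and 12955 genes, each gene being represented by its brightest tested probe. Of 3906 genes with several tested probes, 4 had probes called in opposite directions. Limma's moderated test (lmFit and eBayes, prior degrees of freedom 2.81) compared the 3 replicate log2 ratios with 0, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. A size of at least 2-fold was counted separately. Where one region was above background on none of its arrays, the fold was computed as a lower bound, against the lowest signal above background on each array (2005 genes). Figures were drawn with matplotlib 3.10.9.

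The 30 gene lists, the tests and the 16 alternatives for the counts were fixed before the data were examined. Lists were made from locus identifiers and from words in the descriptions that the files give. Members whose description named an unrelated product were dropped by 11 rules without looking at ratios. The reference table of symbols matched 0 of the loci, so symbols come from the identifiers written with the lists and descriptions from the files. Genome positions were not used here. The 28 lists with at least 5 tested genes were tested with camera (preset correlation 0.01, and a correlation estimated from the data as an alternative), which compares a list with all other genes, and with fry, which tests whether the genes of a list move, on balance, one way, without comparing them with other genes. Camera called 14 of 28 lists with the preset correlation and 0 with the estimated one (smallest adjusted p 0.665). The estimated setting takes its degrees of freedom from the 3 replicates, so it could hardly call any list whatever the correlation. Metal transport, with an estimated correlation of -0.00418, went from an unadjusted camera p of 0.0205 to 0.115. Other estimated correlations were large, with 0.923 for glutelins, 0.787 for the allergens, 0.782 for prolamins and 0.459 for ribosomal proteins. For such lists the preset setting assumes a correlation far below the estimated one. Of the 14 lists that camera called, fry called 10 in the same direction (adjusted p from 0.0168 to 0.0419) and did not call glutelins (0.0511), the respiratory chain (0.0553), histones (0.178) and prolamins (0.362). Of the 14 that camera did not call, fry called 8 (adjusted p from 0.0148 to 0.0419). Toward aleurone these were fermentation, heat shock proteins, cell wall, sucrose transport and cleavage, sugar transporters, vacuolar pumps and aquaporins, and defence. Toward endosperm it was the endosperm regulators.

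The genes named were chosen by a rule fixed before the data were examined. Toward each region it took the 10 described genes with the largest log2 ratio among those past the threshold, with the same sign on all 6 arrays and above background in the higher region on all 6, at most 2 per gene family. From each list it took up to 2 genes toward each region with the smallest adjusted p, or the brightest where none passed, and it allowed all tested members of the starch synthesis and endosperm regulator lists. Exceptions are stated where they occur. Where the lower region was not above background on all 6 arrays, the fold is written as at least that size. If that region was above background on some arrays, the number is the fold of the mean ratio. No bound was computed for such genes, and single replicates can lie below the number.

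The alternatives were no background subtraction, a normexp offset of 16, median centring without loess, between-array quantile scaling of the mean intensities, the scanner software's ratios, the series table, no filter on dim probes, a filter for probes above background in both regions on all 6 arrays, leaving out each replicate, the 6 arrays with a replicate block and dye term, single channels with the array as a random effect, the slide as a term, a trended and robust variance prior, and the mean over a gene's probes. In the block and single-channel fits the lists were tested on the genes' z-scores. After seeing the data, 2 were added, replicate 1 from its first array only, since its dye-swapped array correlated least with the others, and centring on the spike-in probes in place of loess. The dye effect was tested with limma on the 6 arrays with the replicate as a random block.

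The procedure was tested on simulated data with 12955 genes, of which 200 were changed. It called 7 of 67 genes changed 1.5-fold, 38 of 67 changed 2-fold and 58 of 66 changed 4-fold, none in the wrong direction, and 3 unchanged genes. With every gene changed by the size measured here, 33 of 6048 calls were in the wrong direction. A list of 50 genes shifted by 1 log2 unit in the simulation had a camera p of 6.25e-73 and an unchanged list of 50 genes 0.721. Noise was drawn independently for each gene, while the correlation estimated within the real lists reached 0.923 (glutelins). The simulation therefore does not test false list calls among genes that vary together. Replicate spreads were also reassigned at random among the genes, and 200 genes were changed, while 40.0% of genes were called in the real data. The shares of changed genes called in the simulation are therefore not the power of the test in these data.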

Results

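Transcripts of 2 regions of the developing endosperm of rice were compared on 6 arrays, at 7 days after flowering in the japonica cultivar Koshihikari. The endosperm is the storage tissue of the grain. The aleurone is its outer cell layer, which per the labels is enriched in lipid, and the central starchy endosperm is its inside, enriched in starch. Aleurone cells of the dorsal side and central cells were taken by laser microdissection, in which chosen cells are cut out of a tissue section under a microscope. Each array carried both regions, one labelled with the dye Cy3 and the other with Cy5, and each of 3 biological replicates was measured on 2 arrays with the dyes exchanged. The design asks which genes are more active in the lipid-rich outer layer and which in the starch-rich centre.

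Of 41908 gene probes on the array, between 31.8% and 58.3% were well above background in aleurone and between 25.1% and 44.5% in endosperm, depending on the array. Aleurone had more such probes on all 6 arrays. The ratio of aleurone to endosperm probe numbers within an array lay between 1.02 and 1.28 where aleurone carried Cy3, and between 1.54 and 1.99 where it carried Cy5. The 50 brightest probes held 33.3% to 40.6% of the net signal of endosperm and 14.8% to 22.1% of that of aleurone. No spot was saturated. The log2 ratios of the 6 arrays correlated across the tested probes with Pearson's r between 0.738 and 0.960, a correlation across genes, which are not independent replicates. All pairs below 0.890 included the dye-swapped array of replicate 1. For arrays, their number (3 biological replicates) limits the precision.

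**Figure D1:**
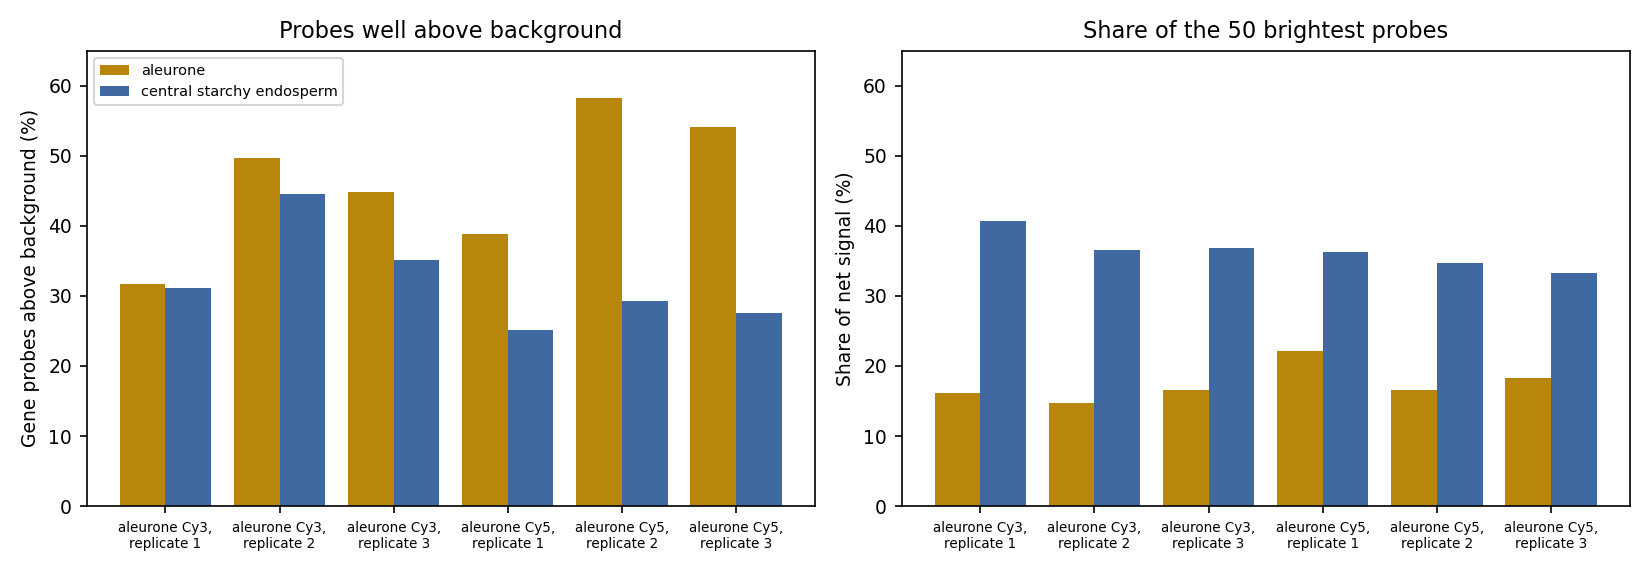
Left, share of gene probes (%) well above background in aleurone (gold) and central starchy endosperm (blue) on each of the 6 arrays, named by the dye of the aleurone sample and by replicate. Right, share of the net signal (%) held by the 50 brightest probes of each region on the same arrays. Aleurone has the taller bar on every array on the left (31.8% against 31.1% at the closest), and endosperm on every array on the right.

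The regions differed in a large part of the genes. Of 12955 genes tested, 2790 were higher in aleurone and 2394 higher in central starchy endosperm, together 40.0% of those tested. A difference of at least 2-fold was found for 1536 genes, 873 higher in aleurone and 663 higher in endosperm. The test was limma's moderated test of 3 replicate log2 ratios against 0, two-sided, at an adjusted p under 0.05 over all probes tested. The unadjusted p was under 0.05 for 3613 genes toward aleurone and 3018 toward endosperm. In aleurone 648 genes were well above background on all 6 arrays and on none in endosperm, against 46 genes in the reverse case. Replicates 1 and 2 were on one slide and replicate 3 on another. Within the first slide alone, which is the same as leaving out replicate 3, 1297 and 1071 genes were called, the second slide held 1 replicate and gives no test, and with the slide as a term 2352 and 1976 genes were called. With the 6 arrays as observations and the replicate as a block, 3371 genes were higher in aleurone and 2790 in endosperm. Without replicate 2 the numbers were 651 and 447, and 897 genes differed by at least 2-fold. The share of calls toward aleurone, 53.8%, varied with the setting. It was 68.1% with median centring and 83.3% with spike-in centring, each in place of the intensity-dependent normalisation, and 41.8% among probes above background in both regions on all 6 arrays (5473 genes tested). The median log2 ratio of all tested genes was 0.05 here, 0.24 with median centring, 0.34 with the scanner software's own ratios, 0.35 with spike-in centring and -0.11 among the probes above background in both regions.

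Ratios are given as log2 of aleurone over central starchy endosperm with their SD over 3 replicates (n = 3), so negative values stand for genes higher in endosperm. Every gene named as higher in a region had the same sign on all 6 arrays. The medians of gene lists varied in size with the setting. Of the 14 lists that camera called, 10 had a median over 1.5 times further from 0 with the scanner software's ratios, 7 with median centring and 8 with spike-in centring, and 7 had one over 1.5 times nearer to 0 with no filter on dim probes. No median of these lists changed sign under the 18 alternatives, of which the filter for probes above background in both regions left 11 of the lists to test. Folds are called "at least" where the lower region was not above background on all 6 arrays, the number of arrays on which it was is given beside the gene, and the ratio of such a gene is not an exact value either.

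The genes with the largest ratios toward aleurone encode oil body and storage globulin proteins, a sucrose carrier and regulators. The transcript of OLE16 (Os04g0546500), an oleosin that coats oil bodies, was 114-fold higher in aleurone (6.84 ± 0.64, adjusted p = 0.000730), and that of OLE18 (Os03g0699000), another oleosin, was 98.7-fold higher (6.63 ± 0.69, adjusted p = 0.000735). A cytochrome P450 gene (Os02g0601500) followed with 5.90 ± 0.44. Genes described as globulin 1 (Os03g0663800) and globulin 2 (Os03g0793700), seed storage proteins, had ratios of 5.86 ± 0.58 and 5.75 ± 0.63, the latter with endosperm above background on 4 of 6 arrays. The single-cysteine peroxiredoxin gene (Os07g0638300), for an antioxidant enzyme, was 46.6-fold higher with the smallest spread of these genes (5.54 ± 0.19, adjusted p = 0.000271). A non-specific lipid transfer protein gene (Os11g0620300) was at least 43.2-fold higher (5.43 ± 0.40, endosperm on 3 of 6 arrays).

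Toward central starchy endosperm the largest ratios belonged to seed allergens, NAC regulators and several enzymes and membrane proteins. The seed allergenic protein genes RAG2 (Os07g0214300) and RA17 (Os07g0214100), of the family of amylase and trypsin inhibitors, were 64.2-fold and 42.1-fold higher in endosperm (-6.00 ± 1.01 and -5.39 ± 0.85, adjusted p = 0.00167 and 0.00142). A prolyl oligopeptidase gene (Os01g0356800) had -5.16 ± 1.01, an early nodulin gene (Os06g0141400) -4.97 ± 0.84 and an alpha-glucosidase gene (Os06g0675700) -4.94 ± 1.17 (aleurone on 2 of 6 arrays). An AWPM-19-like membrane protein gene (Os10g0464300) had -4.91 ± 1.22 and a gibberellin-regulated protein gene (Os05g0432200) -4.64 ± 1.17. A further gene of the inhibitor and lipid transfer family (Os07g0213600) had -4.77 ± 0.91 (aleurone on 2 of 6 arrays). For the limit of 2 genes per family it was counted with lipid transfer proteins, although its description also names amylase inhibitors.

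Genes for oil body and desiccation-related proteins were mostly higher in aleurone. Of 9 oil body protein genes tested, 6 were higher in aleurone and 2 in endosperm, with a median log2 ratio of 1.34, and adjusted over the list alone the counts were 7 and 2. Another oleosin gene (Os09g0324000) was at least 25.2-fold higher in aleurone (4.66 ± 0.39, endosperm on 5 of 6 arrays), whereas 2 genes of caleosins, calcium-binding oil body proteins, were higher in endosperm, Os03g0222600 with -2.76 ± 0.31 and Os06g0254700 with -1.80 ± 0.47 (aleurone on 3 of 6 arrays). The list was shifted toward aleurone by camera (adjusted p = 0.0410), but not without replicate 1 (adjusted p = 0.109) nor with an estimated correlation (adjusted p = 0.665 with an estimated correlation), and its median was 0.44 with no filter on dim probes and 4.02 with the scanner software's ratios. Of 20 genes for LEA proteins and dehydrins, which accumulate in maturing seeds and in drying tissue, 14 were higher in aleurone and 3 in endosperm (median 2.30), and adjusted over the list alone 15 and 3. Em (Os05g0349800) was at least 40.2-fold higher in aleurone (5.33 ± 0.56, endosperm on 5 of 6 arrays) and LEA3 (Os05g0542500) at least 31.7-fold (4.99 ± 0.48, on 3 of 6), while a Lea14-A gene (Os05g0584200) was 7.35-fold higher in endosperm (-2.88 ± 0.45). Camera gave an adjusted p of 0.000244 for this list, and an adjusted p = 0.665 with an estimated correlation. The LEA and dehydrin median was 0.72 with no filter on dim probes and 5.17 with the scanner software's ratios.

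Glutelin and allergen genes were higher in endosperm, and so were a few prolamin genes. Of 14 glutelin genes, which encode the main storage proteins of rice, 13 were higher in endosperm and 1 in aleurone (median -2.99), with the same counts adjusted over the list alone. GluC (Os02g0453600) was 18.2-fold higher in endosperm (-4.19 ± 0.59, adjusted p = 0.00120) and GluB4 (Os02g0268300) 9.31-fold higher (-3.22 ± 0.57, adjusted p = 0.00198). The exception was a gene described only as of the glutelin family (Os08g0482300, 0.81 ± 0.31), whose adjusted p was 0.0908 without replicate 2. All 11 genes of the allergen list were higher in endosperm (median -3.66), adjusted over the list alone as well. Among these were an enolase gene (Os03g0266200, -0.44 ± 0.12), for a glycolytic enzyme, and a thaumatin-like gene (Os07g0419300, -1.09 ± 0.57, aleurone on 2 of 6 arrays), which entered through the word allergen in their descriptions and were singled out after their values were seen. The glutelin list had an adjusted p of 1.36e-05 by camera and the allergen list 6.38e-07, and both had an adjusted p = 0.665 with an estimated correlation. Of 19 prolamin genes, which encode the alcohol-soluble storage proteins, 4 were higher in endosperm and none in aleurone (median -0.84), adjusted over the list alone as well. The largest was Os12g0269200 (-2.35 ± 0.79), and the other 15 had adjusted p of 0.05 or more. Camera gave the prolamin list an adjusted p of 0.00477, and an adjusted p = 0.691 with an estimated correlation. The prolamin median was -0.24 without replicate 3 and -1.29 without replicate 1, and among probes above background in both regions the adjusted p was 0.0850. The members of these families have similar sequences, and signal shared between them was not measured here.

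The globulin list went both ways. Of 11 genes of globulins and related cupins tested, 4 were higher in aleurone and 5 in endosperm, and the same counts came out adjusted over the list alone. Besides globulins 1 and 2, named above, which were higher in aleurone, a cupin gene (Os03g0654700) was 17.2-fold higher in endosperm (-4.11 ± 0.40), as was GluC, which its description also places among the cupins. The alpha-globulin gene (Os05g0499100), singled out after its value was seen as the storage globulin of the starchy endosperm, had -3.63 ± 0.91. The list's median (-0.31, -0.54 without replicate 2 and -0.02 without replicate 3, but 0.10 with spike-in centring and 0.03 with the mean over a gene's probes) and its camera direction were toward endosperm, its mean (0.61) toward aleurone, and camera's adjusted p was 0.794.

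Starch synthesis genes divided between the regions. Of 27 genes tested, 14 were higher in central starchy endosperm and 8 in aleurone (median -0.73), with the same counts adjusted over the list alone. In endosperm the pullulanase gene PUL (Os04g0164900), for a debranching enzyme, was 16.4-fold higher (-4.04 ± 0.72), and both subunits of the endosperm ADP-glucose pyrophosphorylase, which makes the glucose donor for starch, were 15.9-fold (AGPS2, Os08g0345800, -3.99 ± 0.55) and 11.0-fold higher (AGPL2, Os01g0633100, -3.46 ± 0.45). The branching enzyme genes BEI (Os06g0726400, -3.66 ± 0.84) and BEIIb (Os02g0528200, -2.26 ± 0.63) were higher there, and so were the genes of the plastid carriers GPT1 (Os08g0187800, -3.17 ± 0.54) and BT1 (Os02g0202400, -3.09 ± 0.63). The same held for the granule-bound starch synthase GBSSI (Os06g0133000, -2.63 ± 0.83), which makes amylose, the soluble synthases SSIIa (Os06g0229800, -2.20 ± 0.53) and SSI (Os06g0160700, -2.17 ± 0.63), and the plastid phosphorylase PHOL (Os03g0758100, -2.06 ± 0.45). AGPL3 (Os03g0735000, -2.06 ± 0.95), SSIVb (Os05g0533600, -1.31 ± 0.40) and SSIIc (Os10g0437600, -0.73 ± 0.34, aleurone on 5 of 6 arrays) were also higher in endosperm.

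Higher in aleurone were AGPL1 (Os05g0580000, 1.94 ± 0.55), a large subunit of ADP-glucose pyrophosphorylase, the glucanotransferases DPE2 (Os07g0662900, 1.29 ± 0.48) and DPE1 (Os07g0627000, 0.64 ± 0.11), the debranching enzyme ISA3 (Os09g0469400, 0.90 ± 0.31) and the synthase SSIIIb (Os04g0624600, 0.77 ± 0.23). The phosphorylase PHOH (Os01g0851700, 0.66 ± 0.17), BEIIa (Os04g0409200, 0.43 ± 0.24) and AGPL4 (Os07g0243200, 0.40 ± 0.10) were higher in aleurone as well. Endosperm was above background on none of 6 arrays for PHOH (at least 1.58-fold) and AGPL4 (at least 1.32-fold), on 1 for DPE2, on 3 for AGPL1 and SSIIIb, on 4 for BEIIa and on 5 for DPE1. ISA1 (Os08g0520900) had -0.18 ± 0.22, AGPS1 (Os09g0298200) -0.21 ± 0.24, SSIIb (Os02g0744700) -0.21 ± 0.10, FLO6 (Os03g0686900) -0.16 ± 0.15 and GBSSII (Os07g0412100) 0.04 ± 0.03, all with adjusted p above 0.05 (0.109 to 0.658). The list was shifted toward endosperm by camera (adjusted p = 0.00695), and had an adjusted p = 0.665 with an estimated correlation. Its median was -0.47 with no filter on dim probes, -0.44 with spike-in centring, -1.21 with the scanner software's ratios and -2.23 among probes above background in both regions. Without replicate 2, AGPL3, SSIVb, SSIIc and every gene named as higher in aleurone except AGPL1 no longer passed (adjusted p from 0.0531 to 0.203). SSIIc, BEIIa and AGPL4 also did not pass without replicate 3 (0.0679 to 0.115) or with median centring (0.0609 to 0.0784), BEIIa and AGPL4 with the slide as a term (0.0810 and 0.0542), BEIIa with no filter on dim probes (0.0690) and SSIIc with spike-in centring (0.112), and ISA1 and AGPS1 passed toward endosperm without replicate 1 (0.0331 and 0.0216) and with the trended and robust prior (0.0415 and 0.0256). SSIIb passed toward endosperm with that prior (0.0277) and FLO6 with single channels (0.0341).

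**Figure D2:**
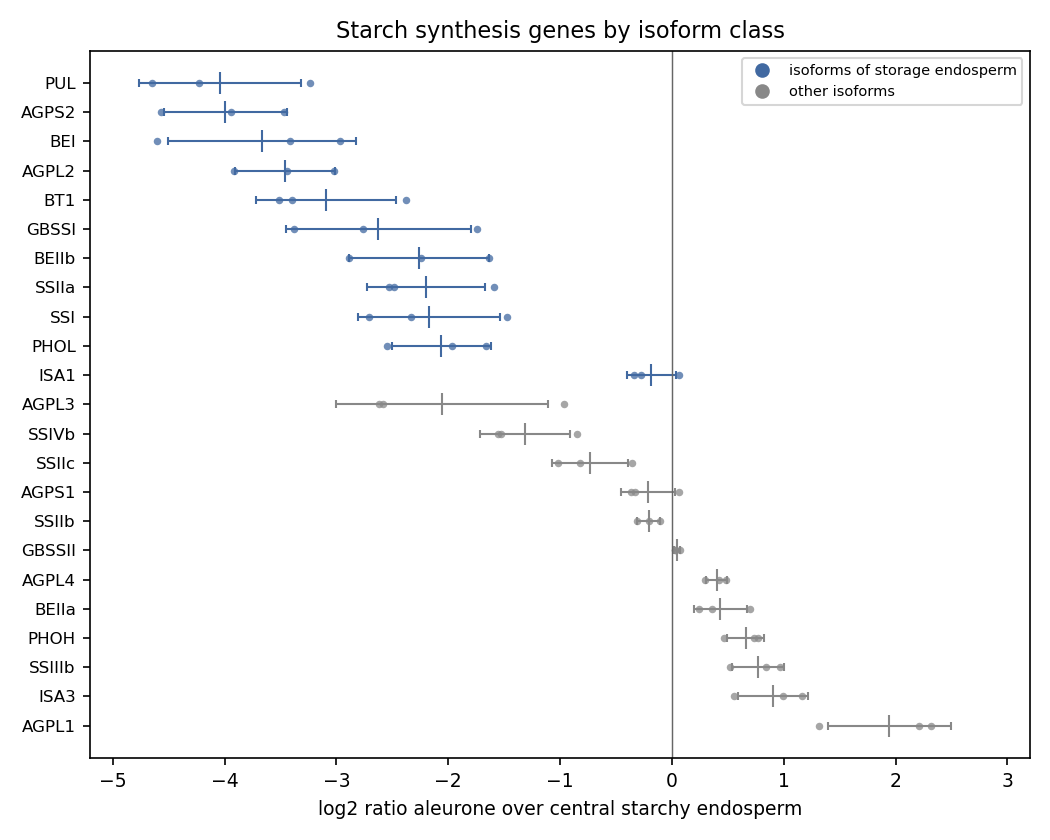
Log2 ratio of aleurone over central starchy endosperm for 23 starch synthesis genes. Points are the 3 replicates, the upright mark is their mean and the bar its SD. The means of isoforms known for storage endosperm (blue) lie between -4.04 and -0.18, those of other isoforms (grey) between -2.06 and 1.94.

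The sucrose and SWEET carrier genes that passed the test were higher in aleurone, and sucrose synthase genes were found on both sides. Of 12 genes tested, 6 were higher in aleurone and 2 in endosperm (median 0.49), and adjusted over the list alone 7 and 2. The sucrose carrier gene SUT1 (Os03g0170900) was at least 49.0-fold higher in aleurone (5.61 ± 0.44, adjusted p = 0.000640, endosperm on 4 of 6 arrays), and SWEET11 (Os08g0535200), a gene of a sugar efflux carrier, at least 12.4-fold (3.63 ± 0.58, adjusted p = 0.00160, on 4 of 6). The sucrose synthase genes SUS2 (Os06g0194900) and SUS4 (Os03g0340500), whose enzymes cleave sucrose, were 11.2-fold and 4.37-fold higher in endosperm (-3.48 ± 0.71 and -2.13 ± 0.31). Camera's adjusted p for the list was 0.161, but 0.0395 without replicate 3 and 0.0252 with spike-in centring. The median was 0.32 without replicate 2, 0.03 with no filter on dim probes and 1.17 with the scanner software's ratios.

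Transcription factors and other regulators of the endosperm had some of the largest ratios in both directions. Of 14 tested, 4 were higher in aleurone and 7 in endosperm (median -0.22, but 0.10 with median centring, 0.21 with spike-in centring and -1.01 among probes above background in both regions), and adjusted over the list alone 5 and 7. NF-YB1 (Os02g0725900) and ERF115 (Os08g0521600) were both at least 41.3-fold higher in aleurone (5.37 ± 0.45 and 5.37 ± 0.54). Endosperm was above background on 1 of 6 arrays for NF-YB1 and on 4 for ERF115. ABI5 (Os01g0859300), a factor of the abscisic acid response, was at least 7.66-fold higher in aleurone (2.94 ± 0.85, endosperm on 1 of 6 arrays) and VP1 (Os01g0911700), a seed maturation factor, 2.44-fold (1.28 ± 0.76). The NAC factor genes NAC20 (Os01g0104500) and NAC26 (Os01g0393100) were 28.1-fold and 27.5-fold higher in endosperm (-4.81 ± 0.64 and -4.78 ± 0.67), and NAC127 (Os11g0512000) 6.77-fold (-2.76 ± 0.35). RPBF (Os02g0252400), a Dof factor that binds the prolamin box of storage protein promoters, had -3.12 ± 0.53. Its partner in storage gene activation, bZIP58 (Os07g0182000), had -1.16 ± 0.27 and GAMYB (Os01g0812000) -1.01 ± 0.25. DEK1 (Os02g0709400), whose calpain-like protein is needed for aleurone identity in cereals, had -0.34 ± 0.06, but -0.03 with median centring (adjusted p = 0.935) and 0.09 with centring on the spike-in probes, and its call was also lost with the slide as a term (adjusted p = 0.0701). TRAB1 (Os08g0472000, 0.41 ± 0.38), NF-YC12 (Os10g0191900, 0.80 ± 0.68) and FIE1 (Os08g0137100, -0.09 ± 0.12) did not pass (adjusted p of 0.0964, 0.0662 and 0.414). Camera gave the list an adjusted p of 0.304. Without replicate 2 the adjusted p was 0.107 for VP1, 0.0507 for GAMYB and 0.147 for DEK1, and without replicate 3 0.176 for DEK1. With median centring it was 0.0550 for VP1 and 0.0643 for bZIP58, and with no filter on dim probes 0.0721 for VP1. NF-YC12 passed toward aleurone under 13 of 18 alternatives, among them leaving out replicate 1 (0.0323) or replicate 3 (0.0405), median centring (0.0411) and the scanner software's ratios (0.0164). TRAB1 passed toward aleurone under 7 of 18, among them leaving out replicate 1 (0.0307), the slide as a term (0.0254) and single channels (0.00675).

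**Figure D3:**
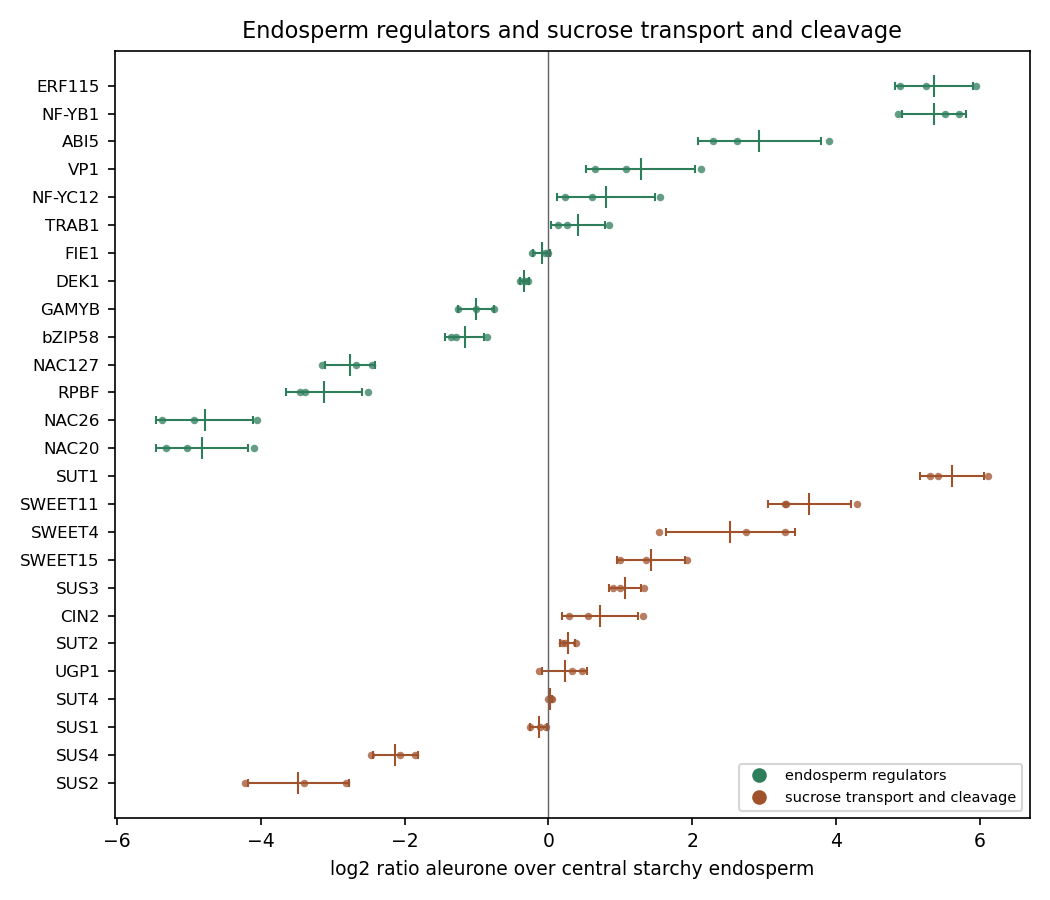
Log2 ratio of aleurone over central starchy endosperm for the 14 endosperm regulators (green) and the 12 genes of sucrose transport and cleavage (brown) tested. Points are the 3 replicates, the upright mark is their mean and the bar its SD. The means of NF-YB1, ERF115 and SUT1 lie above 5, and those of NAC20 and NAC26 below -4.

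Genes for phytate, metal binding and the vacuole included several with large ratios toward aleurone. RINO1 (Os03g0192700), for the inositol phosphate synthase that begins phytate synthesis, was 3.88-fold higher in aleurone (1.96 ± 0.31), and MRP5 (Os03g0142800), for a vacuolar phytate carrier, at least 5.49-fold (2.46 ± 0.59, endosperm on 5 of 6 arrays). Of 9 phytate genes tested, 3 were higher in aleurone and 1 in endosperm, adjusted over the list alone as well. The list's median (-0.10, and -0.06 without replicate 1, but 0.17 with median centring and 0.28 with spike-in centring) and camera direction were toward endosperm and its mean (0.37) toward aleurone, with an adjusted p of 0.951. Of 36 metal transport and binding genes, 11 were higher in aleurone and 4 in endosperm (median 0.17), adjusted over the list alone as well. Metallothionein genes, for small metal-binding proteins, led this list. One of type 2 (Os01g0149200) had the largest ratio of the genes named from it (4.0 ± 0.57, toward aleurone, adjusted p = 0.00124) and one of the EC class (Os10g0542100) was at least 13.0-fold higher in aleurone (3.70 ± 0.32, endosperm on 2 of 6 arrays). Camera gave this list an adjusted p of 0.0410, 0.0833 without replicate 1, and an adjusted p = 0.665 with an estimated correlation. The metal transport list also fell short with the slide as a term (adjusted p = 0.0517), single channels (0.0578), no background subtraction (0.0780), the scanner software's ratios and the series table (0.0917), median centring (0.0969) and no filter on dim probes (0.252, median 0.00). Of 25 genes for vacuolar pumps and aquaporins, 9 were higher in aleurone and 3 in endosperm (median 0.22), and adjusted over the list alone 12 and 3. A vacuolar pyrophosphatase gene (Os05g0156900), for a proton pump, was higher in aleurone (4.0 ± 0.49, adjusted p = 0.000989) and a tonoplast intrinsic protein gene (Os04g0527900), for a water channel of the vacuole, at least 8.48-fold (3.08 ± 0.41, endosperm on 5 of 6 arrays). Camera's adjusted p for the list of vacuolar pumps and aquaporins was 0.113, but 0.0494 with no filter on dim probes and 0.0255 with spike-in centring.

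Lipid genes were shifted toward aleurone. Of 35 genes for fatty acid and triacylglycerol synthesis, 18 were higher in aleurone and 6 in endosperm (median 0.46), and adjusted over the list alone 18 and 7. An acyl carrier protein desaturase gene (Os01g0919900), which introduces a double bond into fatty acids, was 6.30-fold higher in aleurone (2.66 ± 0.15) and an acyl carrier protein gene (Os08g0549300) 2.42-fold (1.28 ± 0.12). A fatty acid desaturase gene (Os11g0104400) was at least 6.61-fold higher in endosperm (-2.73 ± 1.12, aleurone on 4 of 6 arrays), with an adjusted p of 0.0698 without replicate 2. Camera gave an adjusted p of 0.0131, and an adjusted p = 0.665 with an estimated correlation. It was 0.0645 with median centring and 0.0799 with the scanner software's ratios (median 1.56), and the median was 0.10 with no filter on dim probes. Of 26 lipid transfer protein genes, 11 were higher in aleurone and 2 in endosperm (median 0.37), and adjusted over the list alone 14 and 2. Besides the gene named above, Os03g0111300 was 34.1-fold higher in aleurone (5.09 ± 0.47). Camera gave this list an adjusted p of 0.000977, and an adjusted p = 0.665 with an estimated correlation. The lipid transfer protein median was 0.03 with no filter on dim probes and 2.42 with the scanner software's ratios.

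Mitochondrial and antioxidant genes were also shifted toward aleurone. Of 32 respiratory chain genes, 21 were higher in aleurone and none in endosperm (median 0.61), and adjusted over the list alone 22 and none. A ubiquinol-cytochrome c reductase subunit gene (Os06g0175900) was 3.1-fold higher in aleurone (1.63 ± 0.20). Of 25 genes of the TCA cycle, 16 were higher in aleurone and 2 in endosperm (median 0.54), and adjusted over the list alone 18 and 2, with a succinate dehydrogenase gene (Os07g0134800) 4.03-fold higher in aleurone (2.01 ± 0.41). Of 62 redox enzyme genes, 24 were higher in aleurone and 6 in endosperm (median 0.19), adjusted over the list alone as well, led by the peroxiredoxin named above and a glutaredoxin gene (Os04g0508300, 4.65 ± 0.18). Camera's adjusted p was 3.28e-05 for the respiratory chain, 0.000244 for the TCA cycle and 0.00625 for redox enzymes, and all 3 lists had an adjusted p = 0.665 with an estimated correlation. Redox enzymes also fell short with no filter on dim probes (adjusted p = 0.0508, median 0.01), and with the scanner software's ratios the median was 1.17 for redox enzymes and 1.95 for the TCA cycle.

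Genes for ribosomal proteins were broadly higher in aleurone by a modest ratio. Of 254 tested, 179 were higher in aleurone and 6 in endosperm (median 0.75), and adjusted over the list alone 195 and 6. The acidic protein P1 gene (Os08g0116500) was 2.54-fold higher in aleurone (1.34 ± 0.05) and an L41 gene (Os07g0139600) 3.14-fold (1.65 ± 0.20). A gene described as a plastid ribosomal protein (Os04g0461100, -0.66 ± 0.32) was among those higher in endosperm, with an adjusted p of 0.131 without replicate 2 and 0.0848 without replicate 3. Of 45 histone genes, 21 were higher in aleurone and 5 in endosperm (median 0.44), and adjusted over the list alone 23 and 5. Among them an H2B gene (Os01g0153100) was 3.46-fold (1.79 ± 0.39) and an H4 gene (Os09g0553100) 3.40-fold higher in aleurone (1.76 ± 0.50), and an H3.3 gene (Os03g0390600) 1.69-fold higher in endosperm (-0.76 ± 0.08). Of 91 genes of the cell cycle and DNA replication, 14 were higher in aleurone and 15 in endosperm (median 0.10, but -0.26 among probes above background in both regions), and adjusted over the list alone 12 and 15. A gene for an inhibitor of cyclin-dependent kinases (Os02g0762400) had at least a 4.27-fold higher level in aleurone (2.10 ± 0.57, endosperm on 5 of 6 arrays), and a kinesin gene (Os01g0625200), for a motor protein of microtubules, was 4.43-fold higher in endosperm (-2.15 ± 0.31). Camera's adjusted p was 7.75e-17 for ribosomal proteins, 0.00360 for histones and 0.621 for the cell cycle list. Ribosomal proteins had an adjusted p = 0.665 with an estimated correlation, and histones an adjusted p = 0.710 with an estimated correlation. The histone median was 0.72 without replicate 1, and with the scanner software's ratios it was 1.36 and that of ribosomal proteins 1.39. The call of the H3.3 gene was lost with median centring (-0.94, adjusted p = 0.0889) and with the scanner software's ratios and the series table (-0.46, adjusted p = 0.113), and that of the plastid ribosomal protein gene with median centring (0.186), no filter on dim probes (0.0531) and spike-in centring (0.297).

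Genes for protein folding, fermentation and heat shock proteins were found on both sides. Of 14 genes for folding in the endoplasmic reticulum, 3 were higher in aleurone and 5 in endosperm (median -0.09 and -0.06 without replicate 3, but 0.00 without replicate 1, 0.08 with median centring and 0.19 with the scanner software's ratios or spike-in centring), and adjusted over the list alone 5 and 6. The disulfide isomerase gene PDIL1-1 (Os11g0199200) was 3.16-fold higher in aleurone (1.66 ± 0.19), whereas the chaperone genes BiP1 (Os02g0115900) and CNX (Os04g0402100) were 2.71-fold and 1.86-fold higher in endosperm (-1.44 ± 0.22 and -0.89 ± 0.09). Of 17 genes of fermentation and pyruvate use, 9 were higher in aleurone and 5 in endosperm (median 0.47, but -0.14 among probes above background in both regions, 0.05 with no filter on dim probes and 1.61 with the scanner software's ratios), adjusted over the list alone as well. PDC2 (Os03g0293500), for a pyruvate decarboxylase, was 3.74-fold higher in aleurone (1.90 ± 0.12) and the alcohol dehydrogenase gene ADH2 (Os11g0210500), for the next step of ethanol formation, 3.57-fold higher in endosperm (-1.83 ± 0.15). Of 35 heat shock protein genes, 12 were higher in aleurone and 9 in endosperm (median 0.04, and 0.08 with any 1 replicate left out), and adjusted over the list alone 14 and 9. A small class I heat shock protein gene (Os01g0136100) was 17.1-fold higher in aleurone (4.09 ± 0.64) and another small one (Os03g0245800) 5.82-fold higher in endosperm (-2.54 ± 0.88). With median centring the adjusted p was 0.0628 for PDIL1-1 and 0.101 for CNX, and with spike-in centring 0.0762 for CNX. Camera's adjusted p was 0.621 for folding, 0.324 for fermentation and 0.506 for heat shock proteins. Fry, which makes no comparison with other genes, called fermentation (adjusted p = 0.0148) and heat shock proteins (0.0380) toward aleurone, but not folding (0.303).

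Most markers of tissues that could have been taken along were too dim to be tested. So were most loci on the array, of which 12955 of 29690 were tested, so the number of dim markers is no sign of a clean cut. Of 51 photosynthesis genes on the array, a sign of green pericarp, 19 were bright enough to be tested, of which 3 were higher in aleurone and 1 in endosperm (median 0.16, camera's adjusted p = 0.211, and 1.80 and 0.0518 with the scanner software's ratios), and none either way adjusted over the list alone. The chlorophyll-binding protein gene CAB2R (Os01g0600900) and the Rubisco small subunit gene RBCS2 (Os12g0274700) were above background in aleurone on all 6 arrays and in endosperm on none, at least 1.48-fold and at least 1.23-fold higher in aleurone (0.56 ± 0.26 and 0.30 ± 0.02). The adjusted p was 0.0627 and 0.208 without replicate 2, and 0.0868 and 0.169 without replicate 3. CAB2R also did not pass with no filter on dim probes (0.0507), nor RBCS2 with the slide as a term (0.107) or median centring (0.113). Of 3 markers of nucellus, embryo and vascular tissue only MADS29 (Os02g0170300) was tested (0.21 ± 0.12, adjusted p = 0.113, endosperm above background on none of 6 arrays). MADS29 passed toward aleurone with the scanner software's ratios and the series table (2.05, adjusted p = 0.00299), single channels (0.0175) and the trended and robust prior (0.0358). Of 10 alpha-amylase genes, typical of germinating aleurone, 1 was tested (Os04g0403300, -0.16 ± 0.04, adjusted p = 0.154, and 0.0385 with single channels).

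**Figure D4:**
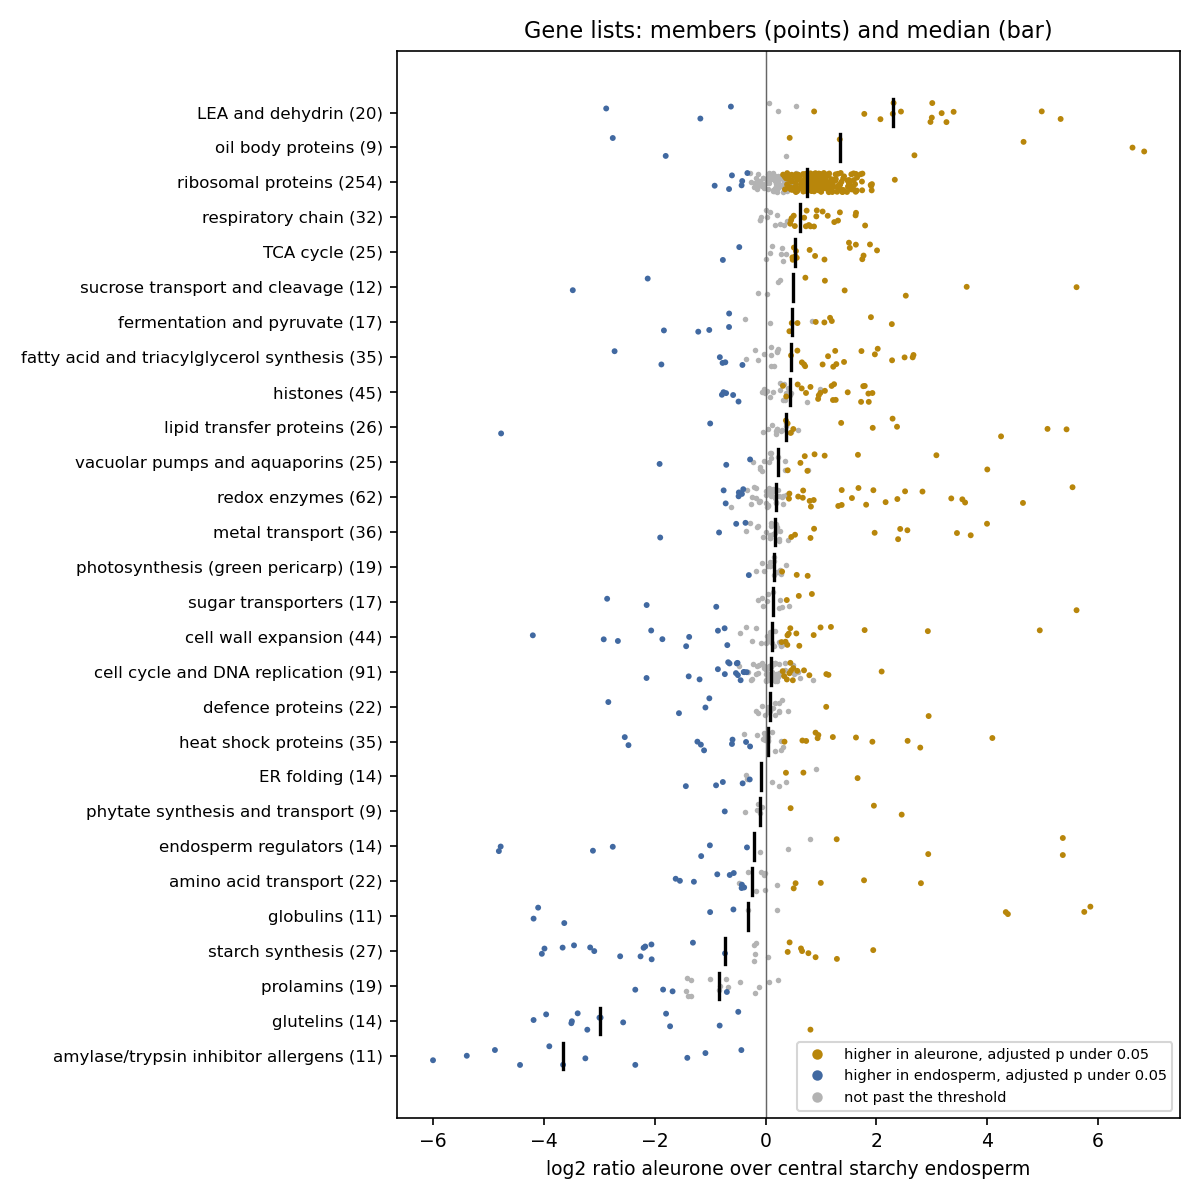
Log2 ratio of aleurone over central starchy endosperm for the tested genes of 28 gene lists, ordered by median, with the number of genes tested in brackets. Each point is a gene, coloured gold (higher in aleurone) or blue (higher in endosperm) where its adjusted p was under 0.05 and grey otherwise, and the bar is the list's median. Medians run from -3.66 for the allergens to 2.30 for LEA proteins and dehydrins.

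The dyes themselves were tested on the 6 arrays with limma. No probe of 18914 differed between dyes at an adjusted p under 0.05, while 5840 had an unadjusted p under 0.05, where chance alone would give 945.7. With single channels fitted and the array as a random effect, limma also called no probe (4317 at an unadjusted p under 0.05). With median centring in place of the intensity-dependent normalisation 4565 probes differed between dyes, 7164 at an unadjusted p under 0.05.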

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

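The tests of the dyes, the total signal and the brightest probes were chosen only after the result was seen.

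Signal was found on probes for microRNAs, which no comparison above uses. Of 510 such probes, 14 were well above background in either region on all 6 arrays (14 in aleurone and 12 in endosperm), against 0 of 24 control probes of random or artificial sequence. So few control probes cannot tell these shares apart. Of 20 microRNA probes bright enough for the test, limma called 3 higher in endosperm, both probes of osa-miR531 (-1.54 ± 0.41 and -1.54 ± 0.46, SD, n = 3, adjusted p = 0.00528 and 0.00624) and 1 of osa-miR166n (-0.39 ± 0.19, adjusted p = 0.0376), and 0 higher in aleurone. The unadjusted p was under 0.05 for 11 with a ratio toward endosperm and for 0 with a ratio toward aleurone. RNA was labelled from an oligo-dT primer, so the probes would read polyadenylated precursors or other transcripts of those sequences, which was not tested.

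More gene probes were above background in aleurone than in central starchy endosperm, by a factor of 1.26, 1.49 and 1.59 in the 3 replicates with the dyes averaged. The dyes are argued against as the whole cause, since aleurone had more such probes on 6 of 6 arrays whichever dye it carried, although the ratio was larger with Cy5. A higher total signal of the aleurone samples cannot be told apart from a wider set of active genes, because the aleurone total was 0.876 times that of endosperm over the replicates (0.575, 0.933 and 1.25 in replicates 1 to 3), without a common direction. A few bright transcripts taking a large part of the endosperm signal may contribute, since without the 50 brightest probes of each region the ratio became 1.14, but at 0.755, 1.22 and 1.59 the replicates again differed in direction. A biological difference between the regions stays open and was not tested separately.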

How the results depend on the processing

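The alternatives that use only the first array of replicate 1 or centre on the spike-in probes were chosen only after the data were seen. No gene called here was called in the other region under any of the 18 alternatives for gene counts. The sign of the ratio did turn for 235 of 5184 called genes with spike-in centring, for 24 with median centring and for at most 2 under any other alternative. Of 2529 values of 143 named genes 2384 kept direction and side of the threshold, 112 fell short of it, 31 newly passed and 2 reversed. Both reversed with spike-in centring, DEK1 (Os02g0709400) to 0.0854 and a photosystem gene (Os04g0236400, a probe shared by 3 loci) to 0.0143, a setting that places the median of all genes at 0.35. The number of genes higher in aleurone moved to 1568 with median centring, 5364 with the scanner software's ratios and the series table alike, 1164 with probes above background in both regions (5473 genes tested), 4526 with single channels, 4346 with the trended and robust prior and 4390 with spike-in centring, and ranged from 651 to 3811 with a replicate left out. Genes higher in endosperm moved to 733 with median centring, 3687 with the trended and robust prior and 878 with spike-in centring, and ranged from 447 to 3125 with a replicate left out. Genes at least 2-fold different moved to 6947 with the scanner software's ratios and the series table and to 929 with probes above background in both regions, and ranged from 897 to 2005 with a replicate left out. Of the 2790 and 2394 genes called, 651 and 447 remained without replicate 2, 1286 and 1064 without replicate 3, 1564 and 726 with median centring and 2782 and 846 with spike-in centring. The smaller set of genes tested lowers the numbers among probes above background in both regions by construction. Spike-in centring, like median centring, also leaves out the loess, so that its effect on the counts is not that of the centring alone. For the other settings the cause was not tested. With the replicate as a block and a dye term, 3371 and 2790 genes were called, 2761 and 2346 of them shared, and the block ended no call of a list or named gene but brought TRAB1 (adjusted p = 0.0390) and NF-YC12 (0.0240) past the threshold. With an estimated correlation 0 of 14 lists stayed past the threshold, with medians of -0.73 for starch synthesis, -2.99 for glutelins, 1.34 for oil body proteins, 2.30 for LEA proteins and dehydrins, -3.66 for the allergens and 0.75 for ribosomal proteins, which this setting leaves as they are. With 3 replicates that setting could hardly call any list, so the lost calls alone do not measure shared variation. The estimated correlation was 0.923 for glutelins and 0.787 for the allergens, but 0.0569 for starch synthesis and -0.0660 for oil body proteins. Where it lies far above the preset 0.01, camera's preset p overstates the evidence if the genes vary together to that extent. The oil body list also fell short with median centring (1.72), the scanner software's ratios and the series table (4.02) and replicate 1 from its first array only (1.54), with medians from 1.03 to 1.54 with a replicate left out, and the cause was not tested. With median centring 4565 probes differed between the dyes. Signal over background limits the ratios of dim probes, for which the offset understates the difference, and the genes that can be tested. Between-array scaling of mean intensities leaves ratios untouched by construction and tests nothing.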

Other observations

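Of the tests in this part, only spike-in centring, one of the scaling alternatives, and the test of dim probes among the starch isoforms were chosen after the result was seen, and the others of the ribosomal genes and starch isoforms were set when the lists' counts were known but not their own results. Amino acid transport genes lay on both sides. Of 22 tested, 5 were higher in aleurone and 9 in central starchy endosperm (median -0.24, but 0.10 with spike-in centring, camera's adjusted p = 0.161), and adjusted over the list alone 5 and 10. An amino acid permease gene (Os07g0134000) was at least 6.99-fold higher in aleurone (2.81 ± 0.44, SD, n = 3, endosperm above background on 1 of 6 arrays), while another permease gene (Os03g0644400) was 3.08-fold higher in endosperm (-1.62 ± 0.64, adjusted p = 0.0104, and 0.0681 without replicate 2). Of 17 sugar transporter genes, 4 were higher in aleurone and 3 in endosperm (median 0.14, but -0.01 with no filter on dim probes, camera's adjusted p = 0.621), and adjusted over the list alone 7 and 3. Besides SUT1 on the aleurone side, a hexose transporter gene (Os01g0133400) was 7.26-fold higher in endosperm (-2.86 ± 0.32).

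Genes acting on the cell wall and in defence also went both ways. Of 44 cell wall genes, 14 were higher in aleurone and 10 in endosperm, and adjusted over the list alone 15 and 11, with a median of 0.11 (0.00 with no filter on dim probes), a mean of -0.04 and an adjusted p of 0.685 by camera toward aleurone. A pectinesterase inhibitor gene (Os04g0587100) was at least 30.9-fold higher in aleurone (4.95 ± 0.31, endosperm above background on 3 of 6 arrays) and a fasciclin domain gene (Os08g0321000) 18.4-fold higher in endosperm (-4.20 ± 0.84). A pectinesterase gene (Os07g0607400), for an enzyme that modifies pectin, was above background in endosperm on 6 arrays and in aleurone on none, at least 7.39-fold higher in endosperm (-2.92 ± 0.68). Of 22 defence genes, 2 were higher in aleurone and 4 in endosperm, adjusted over the list alone as well, with a median of 0.07 (-0.13 among probes above background in both regions), a mean of -0.03 and an adjusted p of 0.797 by camera toward aleurone. A gamma thionin gene (Os01g0932700), for a small antimicrobial peptide, was 7.70-fold higher in aleurone (2.94 ± 0.24), and a class III chitinase gene (Os11g0701100) 7.15-fold higher in endosperm (-2.84 ± 0.85).

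Ribosomal protein genes were higher in aleurone as a group (median 0.75 over 254 genes, 0.70 above the median of all genes). The intensity-dependent normalisation acts on a bias of bright probes beforehand, so lists matched on brightness centre near 0 by construction. The list's median lay at percentile 100 of 10000 such lists of the same size. Their highest median was 0.17, so brightness left after that step did not reach the list's median. Those lists hold genes drawn at random, which need not vary together, so the percentile is no measure of chance. Over 6 alternatives of scaling and background, 4 of them distinct apart from a constant, the list stayed at least 0.80 above the median of all genes. The difference thus did not hinge on the background step or the loess. A scaling constant of an array cancels from it, so it cannot test such a constant. The list's own median was 1.06 with median centring and 1.17 with spike-in centring. The correlation estimated among these genes was 0.459, and how far they simply vary together between samples stays open. Camera's adjusted p of 0.665 with that correlation does not decide this, since with 3 replicates the setting could hardly call any list. Camera's adjusted p of 7.75e-17 assumes the preset correlation of 0.01, far below 0.459, and does not decide it either. A biological difference between the regions stays open and was not tested separately.

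Starch genes appeared to divide by isoform. The 11 isoforms known for storage endosperm had a mean log2 ratio of -2.70 ± 1.12 (SD over genes), with 10 higher in endosperm, and the 12 other isoforms one of 0.05 ± 1.07, with 6 higher in aleurone and 3 in endosperm, a difference of -2.76 that was -2.19, -2.83 and -3.26 in the 3 replicates. A two-sided permutation test over genes gave p = 1e-05, the smallest that 100000 resamples can give. It treats the genes as independent, which genes of a class need not be, so it is no measure of variation between replicates. The storage class was defined by known use in storage endosperm, so its lean toward endosperm was partly given by its definition. Both limits also hold for the permutation test on fewer genes below. Dim probes drawn toward 0 cannot be excluded as a cause. Among the 11 storage and 4 other isoforms above background in both regions on all 6 arrays the difference was -2.04 (-1.80, -1.90 and -2.40 in the replicates, permutation p = 0.00952 over 1365 arrangements), although the mean of those 4 was -0.67. Of the other isoforms higher in aleurone this filter kept only ISA3. AGPL3, SSIVb and ISA3 stayed dimmer (mean log2 intensity 8.06, 8.12 and 8.35) than every storage isoform (PUL lowest with 9.53), so brightness was not matched. A candidate explanation is a hypothesis resting on these tests alone. It is that aleurone cells at this age use more of the isoforms of transient starch in other tissues than central cells do. Among the other isoforms, however, AGPL3, SSIVb and SSIIc were higher in endosperm. AGPS1, SSIIb and GBSSII were not called, nor was ISA1 among the storage isoforms, and signal shared between isoforms was not measured. A ratio toward aleurone also does not make an isoform the main one there. The mean log2 level within aleurone was 13.37 for BEIIb against 7.41 for BEIIa, and 11.01 for AGPL2 against 9.06 for AGPL1. It was 10.41 for AGPS2 against 10.31 for AGPS1, and only 7.54 for the storage isoform PUL. How levels of different probes relate to transcript amounts was not measured.

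As to chance in the gene counts, the signs of 3 replicates form 4 patterns, too few for a share under 0.05. Only 1 pattern, the real one, called 5184 genes and the highest of the others called 0.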
